A study of Mus musculus with 6 samples.

How the data were processed

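The data are RNA-seq of primary mouse bone marrow-derived macrophages in 6 libraries: 2 of untreated cells at day 0, 2 of cells given RANKL for 1 day, and 2 of cells given RANKL and sodium acetate for 1 day. Groups were taken from the sample titles. In each group 1 title ends in the number 1 and is called replicate 1 here, and the title without a number is called replicate 2. Doses of RANKL and acetate are not given in the sources used here. Per the labels' protocols, total RNA was extracted with a miRNeasy kit and treated with DNase, and libraries were made with a SMARTer mRNA-seq kit.

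Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.39, aligned with STAR and quantified with RSEM 1.3.1 on GRCm38 (mm10), and DESeq2 1.26.0 was used. The STAR version and the gene annotation are not given in the sources used here. The authors deposited expected counts, TPM (transcripts scaled to a common total) and FPKM (fragments per kilobase, scaled to a common total) for genes and for transcripts. The deposited expected counts are RSEM's estimates and were not normalized. The deposited TPM are scaled by the authors for transcript length and library total, and the deposited FPKM likewise. The gene table holds 45706 genes, 45143 of which (98.8%) have an identifier in GENCODE M21, and the transcript table holds 109617 transcripts. GENCODE M21 was used here for coordinates, transcript names and sequences, while gene symbols were those of the deposited gene table. Of the gene-level expected counts, 97.1% were within 0.005 of a whole number. Gene-level expected counts were the main values, and gene-level TPM and FPKM entered alternatives. Transcript expected counts were examined for Nfatc1 alone. Their totals also chose the transcript of each gene whose sequence gave GC content and length and was searched for copies of mitochondrial genes. Transcript TPM and FPKM were not used here.

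Expected counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups (minimum count 10, minimum total 15), which left 12224 genes. Libraries were scaled by TMM, with factors from 0.952 to 1.037, and CPM were computed from the scaled totals. A quasi-likelihood model with 1 mean per group was fitted to all 6 libraries, with 3 residual and 29.5 prior degrees of freedom and a common dispersion of 0.00128, a biological coefficient of variation of 3.6%. Contrasts were RANKL against day 0, RANKL with acetate against RANKL, RANKL with acetate against day 0, and the mean of both RANKL groups against day 0. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Fold changes of genes with 0 counts in a group were computed against a floor of 3 counts over the group, and for 1 to 3 counts the ratio of counts per library total is given with an exact 95% counting interval. With 2 libraries against 2, a permutation of labels cannot reach a two-sided p below 0.333, so tests rest on the spread pooled over genes and groups.

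Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over 25 lists per contrast: osteoclast differentiation and resorption, RANK signalling and transcription factors, negative regulators of osteoclast formation, macrophage identity, interferon-stimulated genes, inflammatory mediators, MHC class II, TCA cycle, oxidative phosphorylation, glycolysis, acetate and acetyl-CoA metabolism, short-chain fatty acid receptors and transporters, cholesterol biosynthesis, fatty acid synthesis, LXR targets, histone acetyltransferases, histone deacetylases and sirtuins, cell cycle, ribosome biogenesis and MYC targets, unfolded protein and integrated stress response, NRF2 targets, lysosome and V-ATPase, hypoxia, mitochondrially encoded transcripts, and immediate early and heat shock genes. A further 9 lists hold markers of B, T or NK, neutrophil, erythroid, stromal, endothelial, mast, dendritic and megakaryocyte cells. Named genes are taken from those given by a rule: the 10 raised and 10 lowered genes with the largest fold change among called genes with a mean of at least 10 CPM, separated libraries and an assigned symbol, a panel of 23 genes, and up to 4 members of each list with the smallest adjusted p. Other names, such as the exceptions in a count, Kdr, Cdh5, Ighm, Pf4 and mt-Atp6, and genes in the closing part on further genes, were chosen after their values were seen. The comparisons, their tests, the lists, the panel, the naming rule and the alternatives were chosen before the data were examined. The tests of technical explanations in the closing part were written later, when first results had been seen.

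Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE and upper-quartile factors, no low-count filter, a filter of 5 CPM in 2 libraries, fits of only the groups compared, the replicate number as a block, limma-trend on log2 TPM with a pseudocount of 1 or 0.1 and on log2 FPKM with a pseudocount of 1, a log2 fold change of at least 1, each library left out in turn, and for lists camera with an estimated correlation and fry. A group left with 1 library is assumed to vary like the other groups. Correlations and covariances between comparisons that share libraries, and the calls shared by the RANKL and acetate comparisons, were set beside 20 simulated data sets.

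The steps were tested on simulated counts for the 12224 genes with 200 genes changed. For RANKL against day 0 the test recovered 72 of 100 genes changed 1.5-fold and 88 of 100 changed 2-fold, with 14 false calls. For acetate against RANKL it recovered 67 and 84 of 100, with 7 false calls. Of the 25 lists, 0 were called when unchanged in either comparison. The simulated genes were drawn independently of each other, so this does not show how the list test behaves with correlated genes.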

Results

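Messenger RNA was sequenced from mouse bone marrow-derived macrophages, primary cells that can be driven to become osteoclasts, the multinucleated cells that resorb bone. The 6 libraries form 3 groups of 2. Untreated cells were taken at day 0, and the other cells were taken after 1 day with RANKL, the cytokine that starts osteoclast formation, either alone or together with sodium acetate, the salt of a short-chain fatty acid. Gene-level expected counts totalled 10619528 and 9997515 in the day 0 libraries, 11254944 and 10790705 with RANKL, and 10218460 and 10120498 with RANKL and acetate. Libraries of a group lay close together. The chi-square of their counts per gene was between 1.94 and 2.61, above the 1 that counting noise alone would give, so no pair was counted as 1 sample. Between groups it was 27.15 to 27.38 for RANKL with and without acetate, 100.17 to 104.34 for acetate against day 0, and 157.86 to 165.7 for RANKL against day 0. The first principal component held 80.3% of the variance of log CPM (counts scaled to a common library total) and placed the acetate libraries, at 22.9 and 24.6, between day 0, at -73.4 and -74.0, and RANKL alone, at 50.2 and 49.8. The second component held 10.4% and set the acetate libraries, at -26.5 and -25.0, apart from RANKL alone, at 20.1 and 20.4. The labels do not say that the 2 libraries of a group come from separate cultures or animals, so every p-value measures only the spread between these samples, which may be technical. Counting intervals and floors cover counting error only, because the labels mention no molecular identifiers.

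What 1 day of RANKL changes in these macrophages was asked by comparing the RANKL libraries with day 0. The series has no day 1 group without RANKL. Changes credited to RANKL here and below therefore cannot be told apart from those of the day in culture. Genes of the osteoclast programme rose steeply. Mmp9, a matrix metalloproteinase of osteoclasts (chromosome 2, 164940780 to 164955850 on GRCm38), went from 11.1 ± 0.572 to 1401 ± 2.93 CPM (SD, n = 2 per group), 126-fold. Ctsk, the collagen-degrading cathepsin K (chromosome 3, 95499256 to 95509362), rose 280-fold from 1.18 ± 0.406 to 331 ± 5.11 CPM, and Acp5, the tartrate-resistant acid phosphatase (chromosome 9, 22126727 to 22135711), rose 49.6-fold to 531 ± 6.98 CPM. Nfatc1, the transcription factor that directs the programme (chromosome 18, 80606205 to 80713071), rose 11.1-fold to 523 ± 7.65 CPM. Macrophage genes fell at the same time: Mrc1, the mannose receptor, dropped 24-fold from 1488 ± 33.4 to 62.1 ± 0.618 CPM.

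Of 12224 genes tested, 8106 (66.3%) changed, 4011 up and 4095 down, and 1030 of the raised and 1630 of the lowered genes did so by at least 2-fold. Among 17 tested genes of osteoclast differentiation and resorption, 15 were raised, 1 (Ostm1) was lowered and 1 (Itgb3) was not called, with the same counts when adjusted over the list alone. Dcstamp, which cells need to fuse, rose by 6.28 ± 0.21 on the log2 scale (SE), Atp6v0d2, a proton pump subunit, by 5.94 ± 0.12, and Jdp2, a transcription factor, by 5.17 ± 0.06. Ocstamp, another fusion gene, had 2 counts at day 0 and was 684 times higher with RANKL (counting interval 189 to 5650). Oscar, an activating receptor, had 0 counts at day 0 and 28 with RANKL, at least 8.04-fold higher against a floor of 3 counts over the group. The list's median log2 fold change was 5.63, or 4.23 with genes at 0 counts set to their bound. Itgb3, a subunit of the osteoclast integrin, was at 9.79 ± 1.25 and 10.4 ± 0.971 CPM. Calcr, the calcitonin receptor, had 0 counts in every library. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 2.46e-40 for Mmp9, 1.88e-35 for Ctsk, 4.77e-36 for Acp5, 2.54e-33 for Nfatc1, 1.59e-23 for Dcstamp, 0.000132 for Oscar and 0.68 for Itgb3. The list as a whole was shifted upwards (camera, adjusted p = 1.22e-32; adjusted p = 0.0146 with an estimated correlation).

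**Figure D1:**
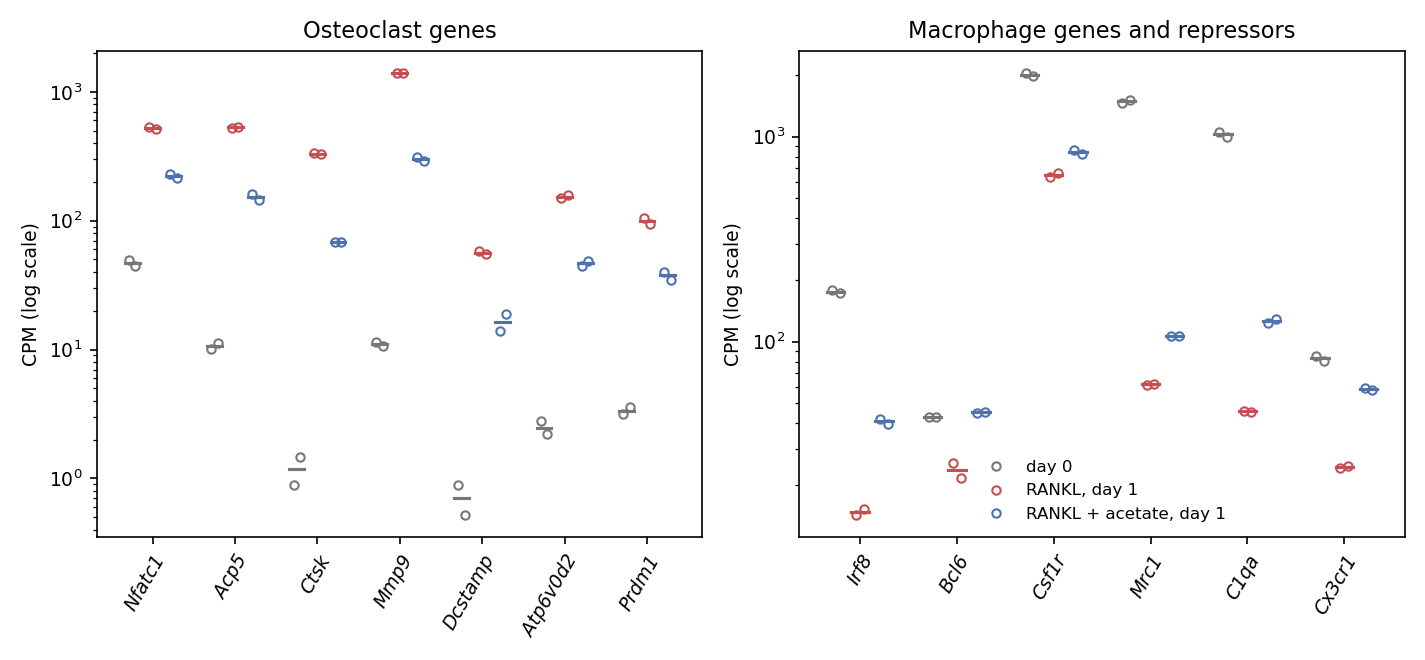
Expression of osteoclast genes (left) and of macrophage genes and repressors of osteoclast formation (right) in CPM on a log axis, with each library as a circle and each group's mean as a bar, for day 0, RANKL, and RANKL with acetate. Ctsk stood at 1.18, 331 and 68.4 CPM in the 3 groups and Irf8 at 175, 14.8 and 40.9 CPM.

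All 21 macrophage identity genes fell with RANKL (21 adjusted over the list alone), by a median of -2.41 on the log2 scale (camera, adjusted p = 7.12e-64; adjusted p = 0.0146 with an estimated correlation). The complement genes C1qa, C1qb and C1qc had log2 fold changes of -4.49 ± 0.05, -3.64 ± 0.04 and -3.96 ± 0.04 (SE, n = 2 per group). Csf1r, the receptor for the macrophage growth factor, fell from 2008 ± 57.3 to 648 ± 19.3 CPM (SD). Among 20 genes of RANK signalling and its transcription factors, 13 rose and 3 fell, over all genes as when adjusted over the list alone, with a median of 1.58 (camera, adjusted p = 2.07e-15; adjusted p = 0.0188 with an estimated correlation). Fos rose by 3.35 ± 0.06, Fosl2 by 3.18 ± 0.05, Nfkb2 by 2.49 ± 0.05 and Prdm1, a repressor of macrophage genes, by 4.89 ± 0.13. Myc rose by 1.82 ± 0.06 and Tnfrsf11a, which encodes RANK, by 0.83 ± 0.05. Of 10 negative regulators of osteoclast formation, 7 fell and 1 rose, as when adjusted over the list alone, with a median of -1.51 (camera, adjusted p = 1.69e-05; adjusted p = 0.0632 with an estimated correlation). Irf8 (chromosome 8, 120736358 to 120756694) fell 11.8-fold, and Id1, Rbpj and Bcl6 fell by 3.81 ± 0.15, 1.22 ± 0.04 and 0.86 ± 0.10. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 6.16e-39 for Mrc1, 1.19e-29 for Csf1r, 5.17e-29 for Irf8 and 1.24e-24 for Myc.

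Sterol synthesis genes fell as a block with RANKL. All 21 cholesterol biosynthesis genes fell (21 adjusted over the list alone), with a median of -1.69 (camera, adjusted p = 4.83e-20; adjusted p = 0.0164 with an estimated correlation). Insig1, which holds back the sterol-sensing machinery, fell from 205 ± 4.83 to 20.4 ± 1.21 CPM, while Cyp51, Fdps and Hmgcs1 fell by 2.87 ± 0.08, 2.74 ± 0.07 and 2.26 ± 0.07. All 20 genes of ribosome biogenesis and MYC targets rose (20 adjusted over the list alone), with a median of 1.38 (camera, adjusted p = 8.34e-21; adjusted p = 0.022 with an estimated correlation). The nucleolar proteins Npm1 and Ncl rose by 1.69 ± 0.04 and 1.60 ± 0.03. Of 11 inflammatory mediators, 7 fell and 4 rose, over all genes and adjusted over the list alone, with a median of -2.45 (camera, adjusted p = 1.1e-08; adjusted p = 0.0345 with an estimated correlation). The chemokines Ccl4, Ccl7 and Ccl2 fell, with log2 fold changes of -4.51 ± 0.11, -4.02 ± 0.05 and -3.16 ± 0.04.

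Several further lists were called by camera with the preset but not with an estimated correlation. Of 19 TCA cycle genes, 16 rose and 1 fell, as when adjusted over the list alone, with a median of 0.37 (camera, adjusted p = 0.014; adjusted p = 0.129 with an estimated correlation), and Idh3a rose by 0.97 ± 0.06. Of 19 nuclear genes of oxidative phosphorylation, 17 rose, or 19 adjusted over the list alone, with a median of 0.31 (camera, adjusted p = 0.0103; adjusted p = 0.123 with an estimated correlation), and Cyc1 rose by 0.81 ± 0.06. Fatty acid synthesis genes fell in 11 of 12 cases, as when adjusted over the list alone, with a median of -0.86 (camera, adjusted p = 1.49e-05; adjusted p = 0.0886 with an estimated correlation), Fads2 by 4.24 ± 0.17. Of 8 LXR targets, 6 fell and 2 rose, as when adjusted over the list alone, with a median of -1.46 (camera, adjusted p = 0.00187; adjusted p = 0.111 with an estimated correlation); Apoe fell by 2.12 ± 0.05 and Abcg1 rose by 1.60 ± 0.07. Lysosome and V-ATPase genes fell in 14 of 20 cases and rose in 4, as when adjusted over the list alone, with a median of -0.69 (camera, adjusted p = 3.08e-05; adjusted p = 0.123 with an estimated correlation); the proteases Ctsd and Ctsb fell by 2.17 ± 0.02 and 1.97 ± 0.02. Of 10 NRF2 targets, 6 fell and 3 rose, as when adjusted over the list alone, with a median of -0.46 (camera, adjusted p = 0.014; adjusted p = 0.13 with an estimated correlation). Hmox1, which breaks down haem, fell by 3.62 ± 0.05, while Gsr rose by 0.84 ± 0.05.

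The other lists were not called between RANKL and day 0, and their members' counts were the same when adjusted over the list alone. Interferon-stimulated genes had 6 of 24 raised and 15 lowered, with a median of -0.22 (camera, adjusted p = 0.359). Cxcl10, an interferon-induced chemokine, rose by 2.12 ± 0.06, while Mx1 and Ifit2 fell by 2.10 ± 0.13 and 1.49 ± 0.07. Cell cycle genes had 20 of 27 raised and 2 lowered, median 0.26 (adjusted p = 0.0576 by camera), with Cdc20 raised by 0.91 ± 0.06 and Ccnd1 lowered by 0.89 ± 0.03. Acetate and acetyl-CoA metabolism had 3 of 12 raised and 9 lowered, median -0.50 (camera, adjusted p = 0.108). Acss1, the mitochondrial enzyme that activates acetate, fell from 48.7 ± 4.36 to 3.29 ± 0.415 CPM (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.26e-21), and its cytosolic counterpart Acss2 fell by 1.62 ± 0.18. Acly, which makes acetyl-CoA from citrate, fell by 0.37 ± 0.04, a call that ended on log2 TPM (adjusted p = 0.0592 by limma) and log2 FPKM, with a range of adjusted p from 1.08e-16 to 0.267 over all alternatives. Short-chain fatty acid receptors and transporters had 2 of 4 raised and 1 lowered, with a median of -0.32, a mean of -0.02 and a test direction of up (camera, adjusted p = 0.359). The monocarboxylate transporter Slc16a1 rose by 1.74 ± 0.08, the receptor gene Ffar3 had 0 counts in every library and Ffar2 had 22 counts over all 6 and did not pass the low-count filter, which also sets a minimum per library. Immediate early and heat shock genes had 4 of 12 raised and 7 lowered, median -1.23 (camera, adjusted p = 0.108), with Atf3 lowered by 3.78 ± 0.12 and Hspa1b raised by 2.49 ± 0.15. Mitochondrially encoded transcripts had 9 of 13 raised and 1 lowered, median 0.28 (camera, adjusted p = 0.216), and MHC class II presentation had 5 of 7 lowered, median -0.53 (camera, adjusted p = 0.429). Glycolysis had 7 of 17 raised and 5 lowered, median 0.04 (camera, adjusted p = 0.434), with Eno1 up by 0.76 ± 0.03 and Pfkp down by -0.71 ± 0.05. Histone acetyltransferases had 2 of 12 raised and 5 lowered, median -0.04 (camera, adjusted p = 0.553), and histone deacetylases and sirtuins 3 of 18 raised and 6 lowered, median -0.05 (camera, adjusted p = 0.603). Hdac9 fell by 4.48 ± 0.16 and the coactivator gene Ncoa3 by 1.32 ± 0.04. Hypoxia targets had 2 of 7 lowered, median -0.24 (camera, adjusted p = 0.677). The unfolded protein and integrated stress response had 5 of 14 raised and 7 lowered, with a median of -0.30 and a mean of -0.20 against a test direction of up (camera, adjusted p = 0.976). Hspa5, an endoplasmic reticulum chaperone, fell by 1.00 ± 0.03 and Shmt2 rose by 1.39 ± 0.05.

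The largest increases with RANKL, among genes with a mean of at least 10 CPM, were in genes with few or no reads at day 0. Scin, an actin-severing protein, had 0 counts at day 0 and 112 ± 3.96 CPM with RANKL (SD, n = 2), at least 736-fold higher against the floor of 3 counts over the group. Mycl, Vegfc and Zfp462 were likewise at least 681, 365 and 260-fold higher. Htra1, Pgf, Car2 and Akap6 had 1 to 3 counts at day 0, with ratios of 492 (counting interval 87.9 to 19500), 467 (83.5 to 18500), 405 (112 to 3350) and 317 (108 to 1540). Car2 is the carbonic anhydrase that supplies protons for resorption. At the other end, Slco2b1 and Fcrls kept 2 counts each with RANKL, at ratios of 0.000954 (counting interval 0.000115 to 0.00345) and 0.0016 (0.000194 to 0.0058). Slc40a1, the iron exporter, fell from 442 ± 5.6 to 4.56 ± 0.0216 CPM. Rnase4, Gas6, Enpp1, Rasgrp3, Rnf150, Cd300e and Ctla2b had log2 fold changes from -6.19 ± 0.08 (Rnase4) to -5.22 ± 0.11 (Ctla2b).

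What sodium acetate changes in cells given RANKL for 1 day was asked by comparing RANKL with acetate against RANKL alone. No group had another sodium salt. Changes credited to acetate here and below may therefore include those of the salt load or of endotoxin carried with the acetate. The osteoclast genes were lower with acetate. Mmp9 fell 4.63-fold from 1401 ± 2.93 to 302 ± 15 CPM (SD, n = 2 per group), Ctsk 4.84-fold from 331 ± 5.11 to 68.4 ± 0.0493 CPM, Acp5 3.46-fold to 153 ± 11.4 CPM and Nfatc1 2.35-fold to 223 ± 13.1 CPM. Macrophage genes were higher: Lyz2, lysozyme, rose 2.46-fold from 3946 ± 30.3 to 9700 ± 77.6 CPM and Siglec1, a macrophage lectin, 4.14-fold to 231 ± 10.7 CPM. Interferon-stimulated genes rose together, led by Cxcl10, which went from 122 ± 0.686 to 680 ± 3.55 CPM, 5.57-fold.

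Acetate changed 3717 of 12224 genes (30.4%), 2040 up and 1677 down, with 452 raised and 183 lowered by at least 2-fold. The number of genes called depended on the method: DESeq2 called 2183 (1341 up, 842 down). Limma-trend on log2 TPM with a pseudocount of 0.1 called 1843 (1127 up, 716 down). Of 17 osteoclast genes, 15 fell (16 adjusted over the list alone) and none rose, with a median of -1.71 (camera, adjusted p = 2.25e-59; adjusted p = 0.00488 with an estimated correlation). Ocstamp fell by 2.08 ± 0.11 on the log2 scale (SE), Dcstamp by 1.77 ± 0.12 and Atp6v0d2 by 1.71 ± 0.07. Oscar returned to 0 counts, at least 8.41-fold lower than with RANKL alone. Itgb3 was at 7.83 ± 0.578 CPM, a log2 difference of -0.41 ± 0.18. The RANK and transcription factor list had 9 of 20 genes lowered and 2 raised (10 and 3 adjusted over the list alone), with a median of -0.15 (camera, adjusted p = 4.47e-09; adjusted p = 0.0341 with an estimated correlation). Prdm1, Fosl2 and Mitf fell by 1.41 ± 0.08, 1.33 ± 0.05 and 0.79 ± 0.06, and Tnfrsf11a and Fos by 0.39 ± 0.05 and 0.36 ± 0.05. Myc was at 196 ± 6.82 CPM against 201 ± 0.208 with RANKL alone. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 1.19e-30 for Mmp9, 5.46e-27 for Ctsk, 1.16e-25 for Acp5, 1.14e-21 for Nfatc1, 6.13e-16 for Prdm1, 0.0876 for Itgb3 and 0.631 for Myc.

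All 21 macrophage identity genes rose with acetate (21 adjusted over the list alone), by a median of 1.21 (camera, adjusted p = 1.21e-59; adjusted p = 0.00751 with an estimated correlation). Fcgr1, a receptor for IgG, rose by 2.44 ± 0.07, Cd14, the endotoxin co-receptor, by 1.65 ± 0.05 and Csf1r by 0.38 ± 0.03. Of the 10 negative regulators, 7 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 0.88 (camera, adjusted p = 2.08e-07; adjusted p = 0.0447 with an estimated correlation). Irf8 rose 2.77-fold from 14.8 ± 0.658 to 40.9 ± 1.78 CPM, while Id1, Bcl6 and Rbpj rose by 1.82 ± 0.18, 0.94 ± 0.10 and 0.82 ± 0.04. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 1.02e-31 for Lyz2, 7.71e-24 for Fcgr1, 1.08e-14 for Irf8, 1.26e-09 for Bcl6 and 4.07e-11 for Csf1r.

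All 24 interferon-stimulated genes were higher with acetate than with RANKL alone (24 adjusted over the list alone), by a median of 1.23 (camera, adjusted p = 3.94e-89; adjusted p = 0.00477 with an estimated correlation). Ifit3, Ifit2 and Rsad2, which restrict viral replication, rose by 2.19 ± 0.07, 2.05 ± 0.07 and 1.91 ± 0.06. Of the 24, 22 were also above day 0, the exceptions being Stat2 and Bst2. Of 11 inflammatory mediators, 9 rose and 1 fell, as when adjusted over the list alone, with a median of 1.40 (camera, adjusted p = 5.92e-24; adjusted p = 0.0106 with an estimated correlation). Ccl7, Ccl4 and Ccl2 rose by 2.56 ± 0.05, 2.52 ± 0.13 and 2.10 ± 0.04, and Nlrp3, the inflammasome sensor, went from 23.6 ± 0.983 to 58.1 ± 4.64 CPM (SD). The adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 6.22e-31 for Cxcl10, 8.49e-23 for Ifit3, 1.22e-22 for Ifit2, 1.76e-28 for Ccl7 and 2e-28 for Ccl2.

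**Figure D2:**
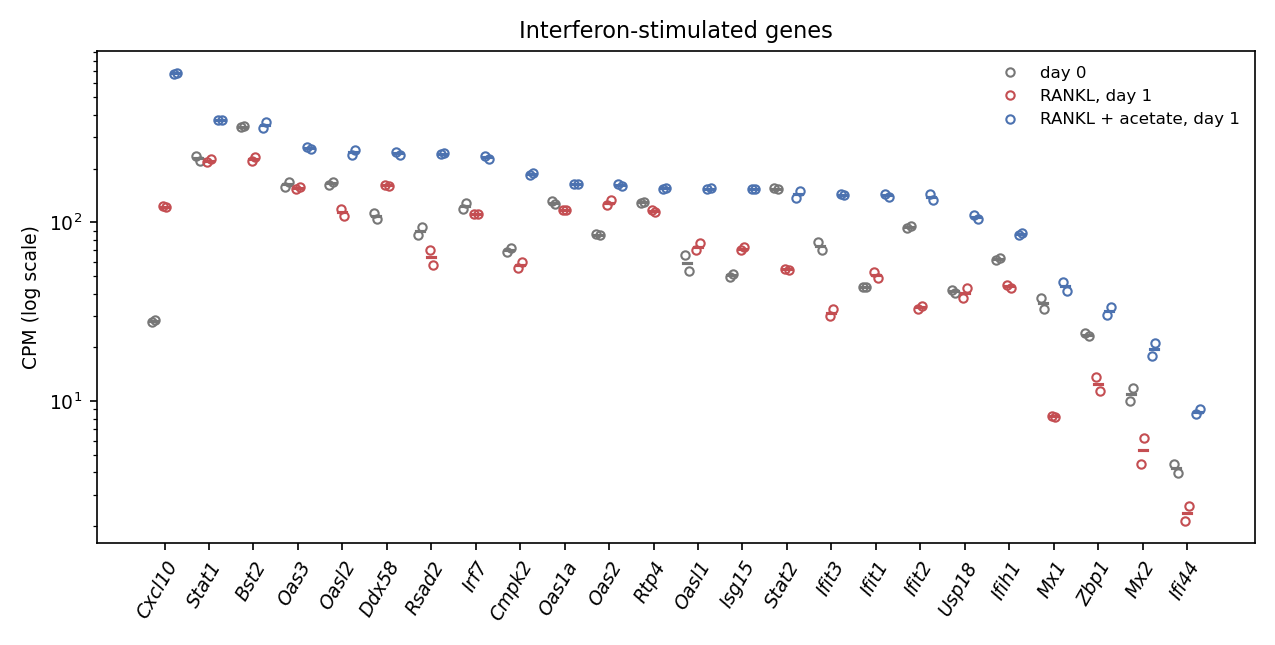
Expression of the 24 interferon-stimulated genes in CPM on a log axis, with each library as a circle and each group's mean as a bar, for day 0, RANKL, and RANKL with acetate. Cxcl10 stood at 28.1, 122 and 680 CPM in the 3 groups and Rsad2 at 89.4, 64.2 and 242 CPM.

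A further 6 lists were called with acetate by camera with the preset correlation but not with an estimated one. Of 21 cholesterol biosynthesis genes, 13 rose and none fell, as when adjusted over the list alone, with a median of 0.31 (camera, adjusted p = 0.00781; adjusted p = 0.133 with an estimated correlation), Pmvk by 0.79 ± 0.15 and Fdps by 0.58 ± 0.08. Of 17 glycolysis genes, 11 rose and none fell, as when adjusted over the list alone, with a median of 0.13 (camera, adjusted p = 0.0147; adjusted p = 0.48 with an estimated correlation). Pfkp, an enzyme that commits sugar to glycolysis, rose by 0.63 ± 0.05, and Slc16a3, a lactate exporter, by 0.61 ± 0.07. The TCA cycle list had 11 of 19 genes lowered and none raised, as when adjusted over the list alone, with a median of -0.16 (camera, adjusted p = 0.0124; adjusted p = 0.142 with an estimated correlation), and oxidative phosphorylation 13 of 19 lowered, or 15 adjusted over the list alone, with a median of -0.14 (camera, adjusted p = 0.00339; adjusted p = 0.132 with an estimated correlation). Sdhb fell by 0.33 ± 0.06, Mdh2 by 0.29 ± 0.04 and Cyc1 by 0.29 ± 0.05. Ribosome biogenesis and MYC targets had 16 of 20 lowered and 1 raised (18 and 1 adjusted over the list alone), with a median of -0.17 (camera, adjusted p = 0.00781; adjusted p = 0.165 with an estimated correlation). Npm1 fell by 0.25 ± 0.03, while Odc1, the first enzyme of polyamine synthesis, rose by 0.74 ± 0.04. Immediate early and heat shock genes had 6 of 12 raised and none lowered (8 raised adjusted over the list alone), with a median of 0.53 (camera, adjusted p = 0.0048; adjusted p = 0.133 with an estimated correlation). Atf3, Klf2, Hspa1a and Hspa1b rose by 1.48 ± 0.15, 1.37 ± 0.15, 1.01 ± 0.16 and 0.97 ± 0.10.

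Of 12 genes of acetate and acetyl-CoA metabolism, 1 rose and 3 fell, as when adjusted over the list alone, with a median of -0.002, a mean of 0.015 and a test direction of down (camera, adjusted p = 0.606). Acss1 was at 3.29 ± 0.415 CPM with RANKL and 3.50 ± 0.156 with acetate, a log2 difference of 0.09 ± 0.25, and Acss2 at 5.04 ± 0.223 and 6.42 ± 0.241, a difference of 0.35 ± 0.21. Acly fell by 0.19 ± 0.04 and Pdhb, a subunit of pyruvate dehydrogenase, by 0.38 ± 0.06. The Acly call ended without replicate 1 of the RANKL group and on log2 TPM, with a range of adjusted p from 0.00017 to 0.0742 over all alternatives. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.825 for Acss1, 0.218 for Acss2 and 0.00112 for Acly. Of 4 short-chain fatty acid receptors and transporters, only Slc16a3 rose, as when adjusted over the list alone, with a median of 0.30 (camera, adjusted p = 0.542). Fatty acid synthesis had 5 of 12 raised and 2 lowered, as when adjusted over the list alone, with a median of 0.15 (camera, adjusted p = 0.383), and the desaturase gene Fads1 rose by 0.82 ± 0.08. Of 8 LXR targets, 2 rose and 1 fell, as when adjusted over the list alone, with a median of 0.12 (camera, adjusted p = 0.782), with Smpdl3a up by 0.48 ± 0.07 and Abcg1 down by -0.49 ± 0.06. Lysosome genes had 10 of 20 raised and 3 lowered (10 and 6 adjusted over the list alone), with a median of 0.16 (camera, adjusted p = 0.0916). Ctsl and Ctsd rose by 0.70 ± 0.03 and 0.49 ± 0.02, and the V-ATPase subunit Atp6v1b2 fell by 0.73 ± 0.04.

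The remaining lists were not called either. NRF2 targets had 4 of 10 raised and 2 lowered (4 and 3 adjusted over the list alone), median 0.02 (camera, adjusted p = 0.347), with Hmox1 and Prdx1 up by 0.86 ± 0.05 and 0.60 ± 0.03. Histone acetyltransferases had 1 of 12 raised and 2 lowered (1 and 1 adjusted over the list alone), with a median of -0.04, a mean of 0.003 and a test direction of up (camera, adjusted p = 0.932), and Ncoa3 rose by 0.45 ± 0.05. Histone deacetylases and sirtuins had 3 of 18 raised and 1 lowered (2 and 1 adjusted over the list alone), median 0.008 (camera, adjusted p = 0.809), with Hdac9 at 2.37 ± 0.2 CPM with RANKL and 6.71 ± 0.102 with acetate (SD) and Hdac1 up by 0.33 ± 0.06. Cell cycle genes had 3 of 27 raised and 2 lowered, as when adjusted over the list alone, median 0.04 (camera, adjusted p = 0.736), with Ccnd1 up by 0.50 ± 0.03 and Cdc20 down by -0.27 ± 0.05. The unfolded protein and integrated stress response had 3 of 14 raised and 2 lowered, as when adjusted over the list alone, median 0.07 (camera, adjusted p = 0.736), with Hspa5 and Xbp1 up by 0.38 ± 0.03 and 0.35 ± 0.06. Hypoxia targets had 2 of 7 raised (3 adjusted over the list alone), median 0.12 (camera, adjusted p = 0.526), with P4ha1 up by 0.45 ± 0.06. MHC class II presentation had 2 of 7 raised, as when adjusted over the list alone, median 0.25 (camera, adjusted p = 0.542). The raised members were H2-Ab1 and Cd74. The H2-Ab1 call ended without replicate 1 or 2 of the RANKL group and without replicate 2 of the acetate group, and the Cd74 call without any one of the 4 libraries given RANKL, and both calls ended with DESeq2 and on log2 TPM and FPKM. Over all alternatives the adjusted p ran from 0.00298 to 0.336 for H2-Ab1 and from 0.0213 to 0.239 for Cd74. Mitochondrially encoded transcripts had 3 of 13 raised and 6 lowered (3 and 7 adjusted over the list alone), with a median of -0.10, a mean of 0.016 and a test direction of down (camera, adjusted p = 0.731). The raised ones, mt-Co2, mt-Co3 and mt-Atp6, have nearly identical nuclear copies whose counts fell, so their values of 0.65 ± 0.06, 0.54 ± 0.06 and 0.36 are uncertain. The mt-Co3 difference was 0.36 without replicate 2 of the RANKL group.

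**Figure D3:**
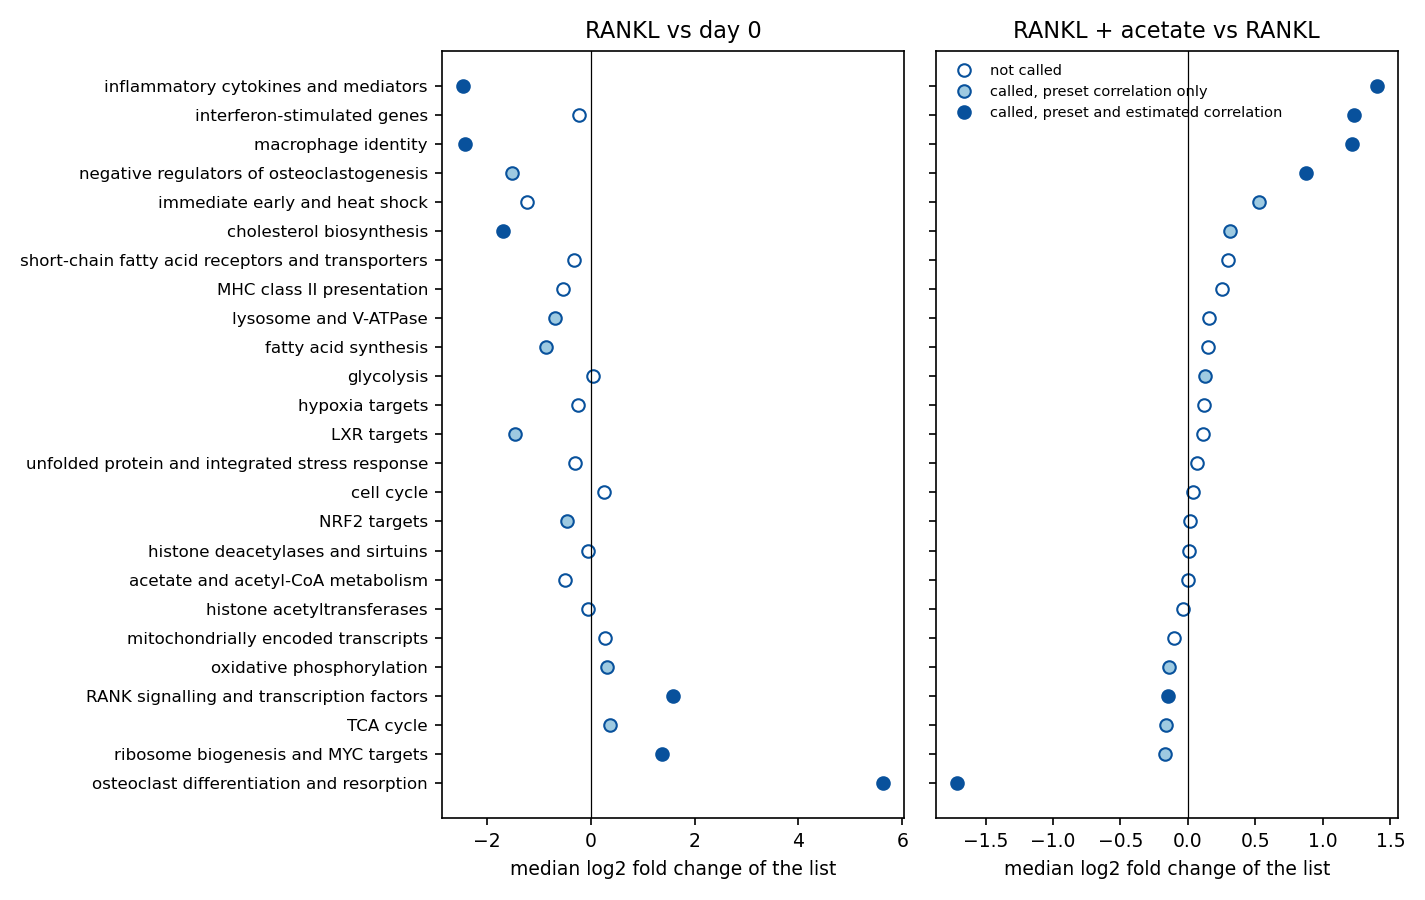
Median log2 fold change of each of the 25 gene lists with RANKL against day 0 (left) and with acetate added to RANKL (right). Open circles were not called, pale circles were called by camera with the preset correlation, and dark circles also with an estimated one; the interferon-stimulated list stood at -0.22 and 1.23 and the osteoclast list at 5.63 and -1.71.

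Besides Fcrls, the largest increases with acetate among genes with a mean of at least 10 CPM were in Slfn4, an interferon-inducible gene, which rose 8.68-fold from 27.5 ± 0.981 to 239 ± 5.26 CPM, in Ccl12 (2.90 ± 0.11 on the log2 scale), Cd300e (2.82 ± 0.40), Irg1, the enzyme that makes itaconate (2.70 ± 0.11), and Ch25h, which makes 25-hydroxycholesterol (2.58 ± 0.15), as well as in Ccl7, Ccl4, Cxcl10 and Fcgr1. Fcrls went from 2 to 20 counts, a ratio of 11.1 (counting interval 2.7 to 97.9), a call that ended without replicate 1 of the RANKL group, without replicate 2 of the acetate group, and on log2 TPM and FPKM with a pseudocount of 1. Its adjusted p ran from 0.000245 to 0.127 over all alternatives. Its log2 difference was 6.35 without replicate 2 of the RANKL group against 3.31 with all libraries. Among the largest decreases were those of Car2 (-2.65 ± 0.15), Adck3 (-2.37 ± 0.15), Slc6a4 (-2.32 ± 0.13), Ctsk, Kbtbd11 (-2.27 ± 0.13), Mmp9, Ocstamp, Akap6 (-2.04 ± 0.13) and Mmp14 (-2.03 ± 0.10). The Car2 call ended on log2 TPM with a pseudocount of 0.1, the highest of its adjusted p over all alternatives, which ran from 5.52e-69 to 0.0583.

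Whether acetate moved RANKL-responsive genes back towards day 0 was asked with genes chosen on the mean of both RANKL groups against day 0, a contrast orthogonal to the difference between them. The 943 genes raised at least 2-fold in that contrast had a median acetate shift of -0.24 (quartiles -0.61 and 0.04), and 72.2% of them lay below 0. Acetate lowered 371 of them and raised 89. The 1388 genes lowered at least 2-fold had a median shift of 0.47 (quartiles 0.15 and 0.93), with 82.8% above 0, 712 raised and 29 lowered. The other 9893 genes had a median of -0.02. By camera, p was 1.27e-12 for the raised and 9.74e-26 for the lowered genes, and 0.000763 and 0.000809 with an estimated correlation. In simulated data with the RANKL effect alone the shifts were -0.000512 and -0.000411. Both RANKL groups had the same means there, so these values show only that the choice of genes brings no shift by itself. On the CPM scale a median of 23% of the RANKL change was undone for these raised genes (quartiles -5.4 and 43.8%) and 12.8% for these lowered genes (4.1 and 22.9%); the choice by the mean of both groups leaves out genes that RANKL changed 2- to 4-fold and acetate returned fully.

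**Figure D4:**
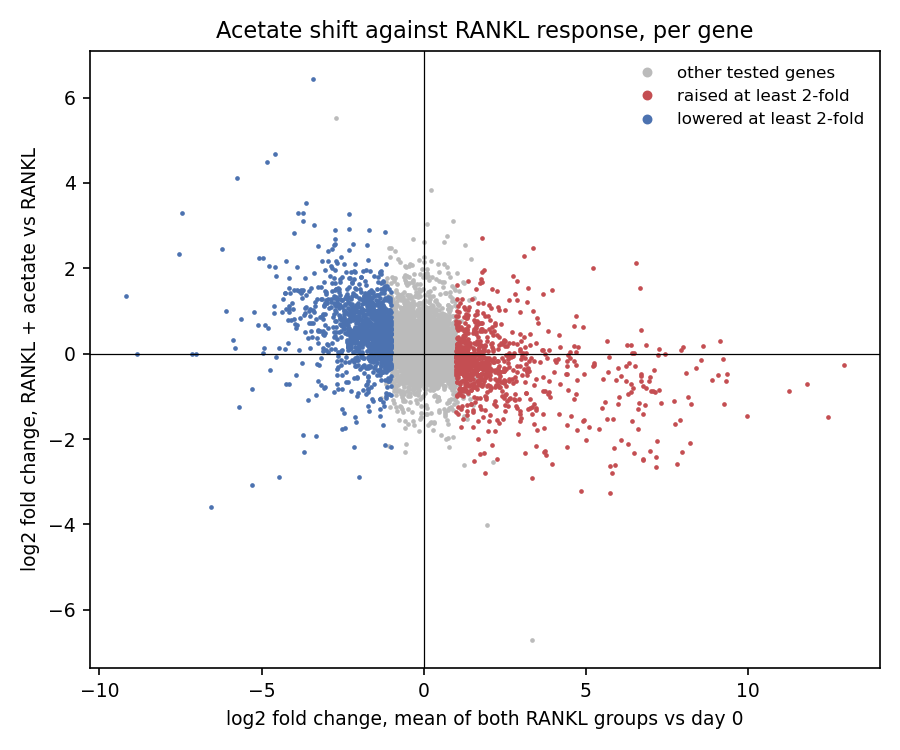
Each point is 1 of 12224 genes, with the log2 fold change of the mean of both RANKL groups against day 0 on the horizontal axis and the log2 fold change of RANKL with acetate against RANKL alone on the vertical axis. Genes raised at least 2-fold (943, red) had a median of -0.24 on the vertical axis, genes lowered at least 2-fold (1388, blue) 0.47 and the others (grey) -0.02.

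Among genes called in both comparisons, 1302 were raised by RANKL and lowered by acetate, where independent lists would share 550, and 1591 were lowered by RANKL and raised by acetate, where independent lists would share 683. In the same direction, 187 were raised by both and 136 lowered by both, against 669 and 562. Each of 20 data sets simulated with the RANKL effect but no acetate effect had 0 genes called with acetate by edgeR and so 0 shared calls. These data sets therefore cannot show how many shared calls the common RANKL libraries alone would bring to real acetate calls. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of -0.57 and a covariance of -0.394. Both comparisons use the same RANKL libraries. Simulated groups with no effect gave a correlation of -0.477 and a covariance of -0.0217, and simulated groups with the RANKL effect but no acetate effect gave -0.0889 and -0.0256.

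The acetate cells were also compared directly with day 0. Ctsk was 57.9-fold, Mmp9 27.2-fold, Acp5 14.3-fold and Nfatc1 4.74-fold above day 0, and Mrc1 14-fold below it. Bcl6 did not differ from day 0 by the test, at 45.2 ± 0.584 against 42.8 ± 0.0986 CPM (SD, n = 2 per group), a log2 difference of 0.08 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.483). In this comparison 7419 genes changed, 3699 up and 3720 down, with 898 raised and 1132 lowered by at least 2-fold. Of the RANKL calls against day 0, 3169 genes were raised and 3295 lowered in both comparisons, where independent lists would share 1214 and 1246. The log2 fold changes had a Pearson correlation of 0.92 and a covariance of 1.328, against 0.517 and 0.0242 for simulated groups with no effect that share the day 0 libraries, and 0.982 and 1.48 for simulated groups with the RANKL effect but no acetate effect.

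Of the 25 lists, 15 were called against day 0. With an estimated correlation 6 of them remained, each at adjusted p = 0.016. Osteoclast genes had 12 of 17 raised and 1 lowered, median 3.84, or 2.83 with genes at 0 counts set to their bound (camera, adjusted p = 2.49e-18), and the RANK list 13 of 20 raised and 4 lowered, median 0.98 (camera, adjusted p = 3.12e-13). Macrophage identity had 18 of 21 lowered and 1, Cd14, raised, median -1.61 (camera, adjusted p = 5.18e-45). Interferon-stimulated genes had 22 of 24 raised, median 0.87 (camera, adjusted p = 1.17e-15), all 21 cholesterol biosynthesis genes were lowered, median -1.43 (camera, adjusted p = 3.32e-23), and all 20 ribosome biogenesis genes were raised, median 1.24 (camera, adjusted p = 1.5e-24). When adjusted over the list alone these counts differed for osteoclast genes (13 raised) and macrophage identity (19 lowered). The other called lists were fatty acid synthesis, median -0.65 (camera, adjusted p = 9.62e-07; adjusted p = 0.0878 with an estimated correlation), LXR targets, -1.16 (0.00021; adjusted p = 0.0878 with an estimated correlation), lysosome, -0.58 (1.61e-05; adjusted p = 0.109 with an estimated correlation), negative regulators of osteoclast formation, -0.78 (0.00456; adjusted p = 0.109 with an estimated correlation), cell cycle, 0.26 (0.00891; adjusted p = 0.109 with an estimated correlation) and NRF2 targets, -0.14 (0.00915; adjusted p = 0.116 with an estimated correlation). Acetate and acetyl-CoA metabolism, -0.64 (camera, adjusted p = 0.0165; adjusted p = 0.241 with an estimated correlation), and glycolysis, 0.24 (0.0247; adjusted p = 0.406 with an estimated correlation), were called as well. Inflammatory mediators had a median of -1.06 and a mean of 0.18, with 6 of 11 lowered and 4 raised (camera, down, adjusted p = 0.00671; adjusted p = 0.109 with an estimated correlation).

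Some genes left the range between day 0 and RANKL alone. Acetate cells stood above both other groups for 475 genes, 83 of them by at least 2-fold against each, and below both for 321 genes, 23 of them by at least 2-fold. Interferon-stimulated genes supplied 22 of the 475, glycolysis 7 and inflammatory mediators 3, while the 3 mitochondrially encoded ones are mt-Co2, mt-Co3 and mt-Atp6, whose values are uncertain. Cxcl10 was 24.3-fold above day 0 and 5.57-fold above RANKL alone, and Slfn4 5.54-fold and 8.68-fold.

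Markers of other cell types in the marrow were checked in the same libraries. A marker counted as detected where it passed the low-count filter, and 0 markers of T or NK cells, erythroid cells, mast cells or basophils, and dendritic cells did so. Of the B cell markers 1 of 7 was, Ighm, at 23.8 CPM at day 0, 2.28 with RANKL and 3.65 with acetate. Neutrophil and precursor markers (7 of 8 detected) had a median log2 fold change of -0.39 with RANKL, 6 of 7 lowered (camera, adjusted p = 0.559), and -0.03 with acetate (camera, adjusted p = 0.659). S100a9, their most abundant gene, had a mean of 53.5 CPM. Stromal or osteoblast markers (3 of 9 detected) had medians of 0.15 and -0.74 (camera, adjusted p = 0.685 and 0.617), and megakaryocyte markers (3 of 4 detected) of 0.04 and -0.004 (camera, adjusted p = 0.163 and 0.961), with Pf4 at a mean of 156 CPM. Against day 0, megakaryocyte markers were shifted down in the acetate cells (camera, adjusted p = 0.0479; adjusted p = 0.339 with an estimated correlation), with Pf4 lowered by 2.23 ± 0.06 while the median was 0.01. The detected endothelial markers (2 of 5), Kdr and Cdh5, moved with the macrophage genes: they fell by 1.33 ± 0.17 and 2.37 ± 0.32 with RANKL and rose by 1.33 ± 0.17 and 1.36 ± 0.36 with acetate.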

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

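The look at Nfatc1 transcripts and the tests for a fixed share of unresponsive cells, for hyperosmotic load, for endothelial or B cells and, in their present form, for reads shared with mitochondrial genes were chosen only after the result was seen, and the bound of the hyperosmotic test was made stricter after its value was known.

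Transcript-level values, which no comparison above uses, showed a change in which Nfatc1 transcripts were counted. Nfatc1-204 held 4.74% ± 0.0768 (SD, n = 2) of Nfatc1 counts with RANKL and 7.09% ± 4.07 with acetate, and 0 counts in both day 0 libraries. Nfatc1-203 held 37.4% ± 3.96 at day 0 and 0 counts in the other 4 libraries. Nfatc1-201 went from 49.6% ± 2.63 at day 0 to 78.7% ± 1.93 with RANKL and 77.3% ± 1.45 with acetate. Grouped by first exon, the transcripts that start upstream held 13% ± 6.58, 21.3% ± 1.93 and 22.7% ± 1.46 of the counts in the 3 groups. The uncertainty of assigning reads to transcripts was not modelled, and no explanation was tested.

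Genes that changed between day 0 and the RANKL groups stood closer to day 0 with acetate. With no day 1 group lacking RANKL, these changes may also come from the day in culture. A fixed share of cells that never responded, acting alone, would undo the same share of every change. Among 804 genes changed at least 4-fold the interquartile range of the share undone spanned 27 percentage points. The median difference within a gene between equally numbered libraries, a different measure of spread, was 6.7. For the 351 of them with a mean of at least 10 CPM these values were 20.9 and 2.8. The share was 79.6% for Ctsk and 63.1% for Nfatc1 but 3.1% for Mrc1 and 1% for Slc40a1. Unresponsive cells together with other effects were not tested. Removing a trend on GC content and transcript length left 128.9% of the shift of the raised genes and 90.7% of that of the lowered genes, and a test of library scaling, later dropped to limit the number of explanations, spoke against a scaling error, since 1 factor cannot move the raised genes by -0.24 and the lowered genes by 0.47. Hyperosmotic load from the added salt stays open. The 6 genes known to rise in hypertonic medium had a median log2 difference of -0.051. The first bound, any median below 0, would have counted this against it. The later bound, below 0 by more than the standard error of the members' mean, was not passed. Values ran from -1.52 ± 0.09 for Slc5a3 to 0.04 ± 0.04 for Slc38a2. Only Slc5a3, lower with acetate, was called, so no rise of these genes was seen. Slc6a12, Slc5a3, Nfat5 and Slc38a2 were already above day 0 with RANKL alone, by 5.025, 3.215, 1.55 and 0.546. Slc6a6 and Akr1b3 were at -0.252 and -0.078. A return of RANKL changes towards day 0 could therefore hide an osmotic rise, so the median cannot decide the question. No group here had another sodium salt. An action of acetate on the RANKL response is a candidate explanation, found on these same libraries and not itself tested. No group had acetate without RANKL, so it cannot be told apart from an effect of acetate that does not need RANKL.

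Interferon-stimulated genes were higher with acetate than in both other groups, 22 of 24 by the test. Neutrophil, stromal or megakaryocyte cells would bring their own markers, but the highest median of these lists against RANKL was -0.004. Of endothelial and B cell markers only 2 and 1 were detected. Kdr and Cdh5 had a median of 1.346 against RANKL. Against day 0, Kdr was at 0.002 ± 0.15, Cdh5 at -1.01 ± 0.28 and Ighm at -2.70 ± 0.20. No detected marker was above day 0. Each of them was lower with RANKL alone than at day 0, so added cells need not lift them above day 0. Endothelial or B cells therefore stay open for the rise above either group, since so few markers were detected. Endotoxin in the acetate stays open. Of 12 genes that macrophages raise strongly with endotoxin, 6 were tested. Of these, 3 (Nos2, Ptgs2 and Slc7a2) were above both groups, at 2.34, 4.53 and 6.76 CPM. That is fewer than the 4 required beforehand and more than the 1 allowed against it. Lcn2, Cxcl2 and Marco were at -0.31 ± 0.19, 0.84 ± 0.43 and 0.66 ± 0.20 against RANKL. Against day 0 they were at -1.05 ± 0.18, -1.60 ± 0.33 and -0.39 ± 0.18. The untested Saa3, Il1b, Il1a, Il6, Il12b and Cxcl1 had at most 4 counts each over both acetate libraries. No strong rise of these untested genes was thus seen, while the 3 genes above both groups went the way endotoxin would move them. A response to acetate itself may also account for the rise, and no group here separates it from endotoxin carried with the acetate.

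Nuclear copies of mitochondrial genes appeared to fall with acetate: of 8 copies, 7 of them on chromosome 1 between 24611535 and 24616197 on GRCm38, 5 were lowered, all on chromosome 1, Gm28437 by 2.19 ± 0.08 and Gm28661 by 1.59 ± 0.08 on the log2 scale. For 3 of them, the copies of mt-Co3, mt-Co2 and mt-Atp6, the sum of copy and parent would have fallen by 0.44 or more with an unchanged parent, but it changed by at most 0.141, which is consistent with reads moving between near-identical sequences in the counting. For the other lowered copies, Gm28439 and Gm29216, reads shared with the parent stay open, since the parent is so abundant that the sum could change by at most 0.039. The raised copy Gm28438 and its parent mt-Nd3 summed to -0.259, the largest change of any pair. Less nuclear or genomic DNA in the libraries was taken to lower other predicted genes too, but their share of counts rose from 0.866% to 0.932%, a change of 7.7%. These genes were not chosen for a lack of transcription. Their share was also lower at day 0, at 0.738% and 0.753%, than with RANKL, at 0.871% and 0.86%. The share therefore cannot decide whether DNA plays a part, and no biological explanation was tested.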

How the results depend on the processing

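No test here was chosen after the result was seen. The acetate shifts kept their direction and call under every alternative, from -0.264 to -0.218 for genes raised by RANKL and from 0.398 to 0.513 for genes lowered by it. Requiring a log2 fold change of at least 1 left 2660 changed genes (1030 raised, 1630 lowered) for RANKL against day 0, 635 (452, 183) for acetate against RANKL, 2030 (898, 1132) for acetate against day 0 and 2331 (943, 1388) for the mean of both RANKL groups, since the criterion is stricter by construction. For acetate against RANKL, DESeq2 called 2183 genes (1341, 842), all among the 3717, log2 TPM with a pseudocount of 1 1908 (1137, 771), with 0.1 1843 (1127, 716), and log2 FPKM 1998 (1100, 898); the cause was not tested. Leaving out 1 library, with the lone library of its group assumed to vary like the other groups, gave 1087 to 1689 genes lowered by acetate. The correlation of both responses was -0.47 with DESeq2 and -0.471 with no filter, which add genes with few counts, -0.636 with a filter of 5 CPM, and -0.584 to -0.478 without 1 library. With an estimated correlation 6 lists were called in each of the 3 comparisons, against 13, 12 and 15, and fry, which does not set a list against other genes, called 24 for RANKL against day 0 and 20 for acetate against RANKL. Log2 FPKM put the median of all genes for RANKL against day 0 at 0.106, and the share of raised calls there was 58.1% instead of 49.5%.

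The named genes gave 4293 values under alternatives, of which 4167 kept direction and call, 113 lost the call, 4 gained it and 9 changed sign. The 9 are H2-DMa, acetate against RANKL, 0.60 with counts, -0.054 and -0.067 on log2 TPM (pseudocount 1 and 0.1) and -0.061 on log2 FPKM; Sdha, a called decrease of -0.18 with counts, 0.033, 0.033 and 0.016 in the same order; Itgb3, RANKL against day 0, which without 1 library ran from -0.038 to 0.225; and Acss1, acetate against RANKL, from -0.036 to 0.22. The gene lists gave 750 values, with 693 kept, 22 losing and 30 gaining a call and 5 turning their test direction: the stress response list, RANKL against day 0, with fry (median -0.298) and without replicate 1 of day 0 (medians without 1 library -0.325 to -0.258); and without 1 library histone acetyltransferases (-0.077 to 0.026) and mitochondrially encoded transcripts (-0.135 to -0.068), acetate against RANKL, and hypoxia targets, acetate against day 0 (-0.083 to 0.071). The cause was not tested.

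The replicate numbers did not pair the libraries: the correlations of deviations of equally numbered libraries were -0.027, -0.063 and -0.007. With the replicate number as a block, 8028 genes changed with RANKL, 3611 with acetate, 7371 between acetate and day 0, and 8080 for the mean of both RANKL groups. A fit of only the groups compared is not defined for that mean. Depth limits what can be said of genes such as Oscar and Ffar2, which have few counts.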

Other observations

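The genes of this part were chosen only after the result was seen, most of them for lying at least 2-fold above or below both other groups, and so was the hyperosmotic test that Slc5a3 belongs to.

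Of the 83 genes that stood at least 2-fold above both day 0 and RANKL alone with acetate, some lie outside the interferon list, and no theme among them was tested. Irg1, which makes the antibacterial metabolite itaconate, was at 7.93 ± 0.408 CPM at day 0, 10.7 ± 0.463 with RANKL and 70.0 ± 2.52 with acetate (SD, n = 2 per group). Clec4e, a receptor for fungal and mycobacterial glycolipids, went from 30.7 ± 1.42 and 44.7 ± 4.46 to 108 ± 0.985 CPM. The guanylate-binding protein gene Gbp2 and the DNA-sensor family gene Pyhin1 were 1.28 ± 0.14 and 1.83 ± 0.09 above RANKL on the log2 scale (SE). Tmem26 rose at each step, from 3.18 ± 1.39 at day 0 to 29.9 ± 1.58 with RANKL and 84.7 ± 6.02 CPM with acetate.

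By at least 2-fold, 23 genes were below both groups. St6gal1, which adds sialic acid to glycoproteins, was at 73.6 ± 0.0604 CPM at day 0, 29.9 ± 0.222 with RANKL and 9.93 ± 0.0527 with acetate, and Fam198b at 29.2 ± 2.44, 18.2 ± 2.69 and 8.27 ± 0.506 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p against RANKL was 2.82e-13 for St6gal1, 3.17e-07 for Fam198b, 2.1e-20 for Irg1 and 3.07e-15 for Tmem26. Slc5a3, a carrier of the osmolyte inositol, rose from 7.72 to 71.9 CPM with RANKL and stood at 25 CPM with acetate.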
